A study of Mus musculus with 38 samples.

How the data were processed

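RNA-seq and ATAC-seq had been run on cortical collecting ducts (CCDs) microdissected from mouse kidney. Per the labels, wild-type mice had been infused for 5 days with saline or with dDAVP, a synthetic agonist of the V2 vasopressin receptor, giving 4 saline and 4 dDAVP RNA-seq libraries and 3 saline and 3 dDAVP ATAC-seq libraries. A separate RNA-seq table held 24 libraries whose titles gave 3 libraries for each of the numbered units WT 1 to WT 4 and MT 1 to MT 4, where MT stands for a β-catenin S552 mutation. Groups were taken from the titles. The labels of these 24 libraries conflicted: every one carried a dDAVP treatment and the genotype C57BL/6, only the titles separated WT from MT, and the name of the deposited table said that no vasopressin had been given. The title of the dDAVP RNA-seq library 4 gave its CCD number as 4 and its dDAVP number as 3. The labels did not say that a unit number stood for one animal.

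The RNA-seq libraries had been made with the SMARTer V4 and Nextera XT kits, per the labels' protocols. STAR and RSEM were named without versions in the submitters' processing notes, with the mouse build mm10. Both RNA-seq tables held TPM, a measure of transcript abundance normalised by the authors for transcript length and library total. Per the file headers, the dDAVP table listed only genes whose lowest TPM over the 8 libraries was above 10, which left 5035 genes. The lowest TPM per library lay between 10.01 and 10.38 and the listed TPM summed to between 895155 and 925759 per library. That table also held 8 log2 copies of the per-library columns, which were not used, and the authors' own log2 fold change, adjusted p-value from DESeq and a mark for Wnt/Fzd target genes, whose criterion was not stated. The β-catenin table listed 55416 genes with TPM deposited by the authors. TPM keeps no record of depth, so the depth of each RNA-seq library was unknown and no counting interval was given.

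For ATAC-seq, cutadapt 3.4, Bowtie2, SAMtools, Picard, bedtools, MACS2, deepTools and DiffBind were named in the submitters' processing notes, and which settings were used was not stated. The deposited table gave, for each of 270806 peaks on mm10, the log2 mean normalised signal of each group with a floor at 0, the log2 fold change of dDAVP over saline, and the authors' unadjusted and adjusted p-value. From the values, the fold change exceeded the difference of the group signals by a median of 0.11 in peaks above the floor. Values per library were not used here because the table gave group means only. The ATAC-seq comparison therefore rests on the authors' deposited values, with no test of its own and with depth unknown.

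Each RNA-seq comparison was tested with limma 3.58.1 (eBayes with a trend) in R 4.3.3 on log2 of TPM plus a pseudocount of 1, for genes with a mean TPM of 1 or more, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. In the β-catenin table the mean TPM over the 3 libraries of a unit was the replicate, giving 4 WT against 4 MT units and 15013 genes tested. In the dDAVP table the minimum removed no gene. Lists of genes fixed before the data were examined, 37 in number, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists that had 5 or more measured members. These were 22 lists in the dDAVP table, with 15 below the minimum, and 34 lists in the β-catenin table, with 3 below it. Camera compares the members of a list with all other genes. For 11 list scores, the mean over members of log2(TPM + 1), the groups were compared with a two-sided exact permutation test over the 70 assignments of 8 samples, adjusted over the 6 or 5 scores of a table. Its smallest possible p was 0.0286.

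The named genes were chosen by a fixed rule. It took the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, or all if fewer passed. With fewer than 10 in total, it took the 10 genes of smallest p. It added Aqp2, Aqp3, Aqp4, Avpr2, Scnn1a, Scnn1b, Scnn1g, Ctnnb1, Axin2, Lef1, Slc26a4 and Slc4a1 in every comparison, up to 4 members of smallest p for each list described, the 5 largest gains and 5 largest losses among the ATAC-seq peaks, and the promoter peaks of the 12 fixed genes. The condition on non-overlapping groups could not be applied to the ATAC-seq table, which gives group means only. Predicted gene models were counted and left unnamed in the RNA-seq comparisons. Gene positions came from the annotation of GRCm38.p6, the same build as mm10, on which 98.9% of the tested symbols of the dDAVP table and 92% of those of the β-catenin table were placed. A promoter peak was one that the deposited table itself annotated as promoter-TSS, and each gene was given its promoter peak of highest signal.

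Changes in accessibility and expression were compared by Spearman correlation across genes, which are not independent replicates, and by setting the median of a gene set against 10000 random sets of the same size matched on promoter signal in 10 bins. The β-catenin and dDAVP effects were compared by Spearman correlation across genes. Figures and peak tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and files were read in R with jsonlite 2.0.0.

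The tests were run first on simulated data. For the dDAVP comparison, with 200 of 5035 genes changed, 44% of the genes changed by a log2 of 1 and 91% of those changed by a log2 of 2 were recovered, with 3 false among 138 calls. For MT against WT, with 200 of 15013 genes changed, 80% and 90% were recovered at these sizes, with 10 false among 180 calls. Neither gave a call when no gene was changed. Camera called a shifted list and 0 of 100 unshifted lists in each comparison, in noise simulated independently for each gene. Real genes are correlated, so this does not show how often camera calls lists falsely in these data. Of 20 simulated promoter sets per shift, all 20 were placed outside the 95% range of the random sets at a shift of 0.5 and at a shift of -0.5, and 1 was at a shift of 0.

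Alternatives covered the pseudocount, the filter on low values, rescaling by median of ratios, quantile normalization, a robust fit, a replicate block by number, each replicate left out in turn, 24 libraries in place of 8 units, an estimated correlation for the lists, and a stricter threshold for the peaks. Methods for read counts were planned for tables of counts and were not used here. The 8 samples of each RNA-seq table were also split in all 35 ways into 4 and 4.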

Results

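The series measured RNA and chromatin accessibility in mouse CCD, the kidney segment in which vasopressin sets water reabsorption. RNA-seq compared 4 saline with 4 dDAVP libraries from wild-type mice after 5 days of infusion, and ATAC-seq compared 3 saline with 3 dDAVP libraries. A separate RNA-seq table compared 4 WT with 4 MT units of 3 libraries each. Depth was unknown for every library. In the dDAVP table, saline libraries 3 and 4 had the lowest median correlation with the other libraries, 0.863 and 0.839, against 0.913 to 0.934 for the remaining 6. Transcripts of neighbouring nephron segments stood high in single libraries: Umod, a thick ascending limb gene, reached 5253 TPM in dDAVP library 1 against 20.95 to 824.9 TPM in the others, and Slc34a1, a proximal tubule gene, reached 2286 TPM in saline library 3 against 27.17 to 426.5 TPM in the others. None of 5 measured proximal tubule markers passed in the dDAVP comparison (camera adjusted p = 0.795, and lower at adjusted p = 0.0147 without saline library 4). In the β-catenin table, 13556 to 16050 genes per library were above 1 TPM.

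The question of the dDAVP comparison was what an excess of vasopressin signalling does to gene expression in the CCD. Aqp2, the water channel of the apical membrane of principal cells (ENSMUSG00000023013, chromosome 15, 99579056 to 99584545), rose 3-fold, from 20170 ± 1573 to 60870 ± 8577 TPM (SD, n = 4 per group), with a log2 fold change of 1.59 (SE 0.18, limma adjusted p = 0.0028). It made up 1.81 to 2.19% of the saline libraries and 5.18 to 7.23% of the dDAVP libraries. Aqp3, a water channel of the basolateral membrane, rose 2.03-fold, from 3875 ± 966.3 to 7732 ± 614.1 TPM (SD, n = 4, adjusted p = 0.0241). Among genes that passed, the largest rise was that of Crem, a cAMP-responsive transcription factor (chromosome 18, 3266354 to 3337773), from 61.32 ± 34.43 to 355.7 ± 40.57 TPM, or 6.29-fold (log2 2.65, SE 0.31, adjusted p = 0.0028). Scnn1a, which encodes the α subunit of the epithelial sodium channel, fell to 0.49 of its saline level, from 281.8 ± 24.53 to 138.7 ± 23.1 TPM (log2 -1.03, SE 0.17, adjusted p = 0.0215).

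Among the other large rises, Abhd3, a phospholipase, rose 5.94-fold (log2 2.57, SE 0.19, n = 4, adjusted p = 7.22e-05). Car15, a membrane-bound carbonic anhydrase (chromosome 16, 17835276 to 17838186), had the smallest adjusted p, 4.82e-05, and rose from 1553 ± 207 to 7701 ± 1174 TPM. Lcn2, a secreted lipocalin also known as a marker of tubule injury, rose 5.02-fold to 475.8 ± 69.77 TPM (adjusted p = 0.00544). The rises of Stc1, a secreted glycoprotein hormone, Niban1, Scg5, Eva1b, Cdk18 and Arg2, the mitochondrial arginase, had log2 fold changes of 2.49, 2.45, 2.45, 2.43, 2.35 and 2.13. Of the 7 genes that fell, Id2, an inhibitor of helix-loop-helix transcription factors, fell most, from 569.4 ± 117.4 to 168.1 ± 33.85 TPM (log2 -1.75, SE 0.21, adjusted p = 0.0032). Tmem52b, Slc16a5, Tmem37, Car12, a carbonic anhydrase, and Ckmt1, a mitochondrial creatine kinase, fell with log2 fold changes of -1.60, -1.40, -1.31, -1.0 and -0.81. The other genes that rose included Dab1, Ache, Btc, Ddit4l, Atp4a, Fads1, Prom1, Mal2, Ly6e, Ctsh, Jpt2, Adh1, Ldha, Wfdc2 and 1 predicted gene model, and these lie outside the rule for named genes.

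Of 5035 genes tested by limma, 35 passed, 28 higher and 7 lower, with folds between 1.75 and 6.29 for the genes that rose or, inverted, fell. At an unadjusted p below 0.05 there were 553 genes, against 252 by chance. The groups did not overlap for 432 genes, 8.58% of those tested, where chance gives 2.86%. The authors' deposited table called 52 genes, 36 higher and 16 lower, and 32 of the 35 were among them, all but Tmem37, Ckmt1 and Wfdc2. The count was 18 without saline library 1, 17 without saline 2, 16 without dDAVP 1, 23 without dDAVP 2, 7 without dDAVP 3 and 19 without dDAVP 4. Of the 19 named genes that passed, 7 passed in each of the 8 fits that left out 1 library: Aqp2, Crem, Abhd3, Niban1, Cdk18, Car15 and Id2. Of these fits, Scg5, Eva1b and Lcn2 lost the call only in the one without dDAVP library 3 (adjusted p = 0.0596, 0.0766 and 0.0593). With a replicate block by number, 12 of the 19 lost the call, among them Scg5, Eva1b and Cdk18 (adjusted p = 0.0989, 0.0792 and 0.0576), and Aqp2, Crem, Abhd3, Niban1, Lcn2, Car15 and Id2 kept it. The calls of Stc1, Arg2, Tmem52b, Slc16a5, Tmem37 and Ckmt1 were lost without saline 1, without saline 2, without dDAVP 3 and in further fits, with adjusted p up to 0.146, 0.111, 0.0962, 0.0865, 0.104 and 0.124. Under quantile normalization Aqp2 had a log2 fold change of 0.42 (adjusted p = 0.696, from 2.54e-05 over 17 alternatives). It held rank 1 in 7 of the 8 libraries, where the method gives equal values, and rank 2 in saline 3. The fold change left by the method therefore came from saline 3 alone. Ckmt1 also lost its call (adjusted p = 0.0606, between 0.0213 and 0.157 over 17 alternatives).

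**Figure D1:**
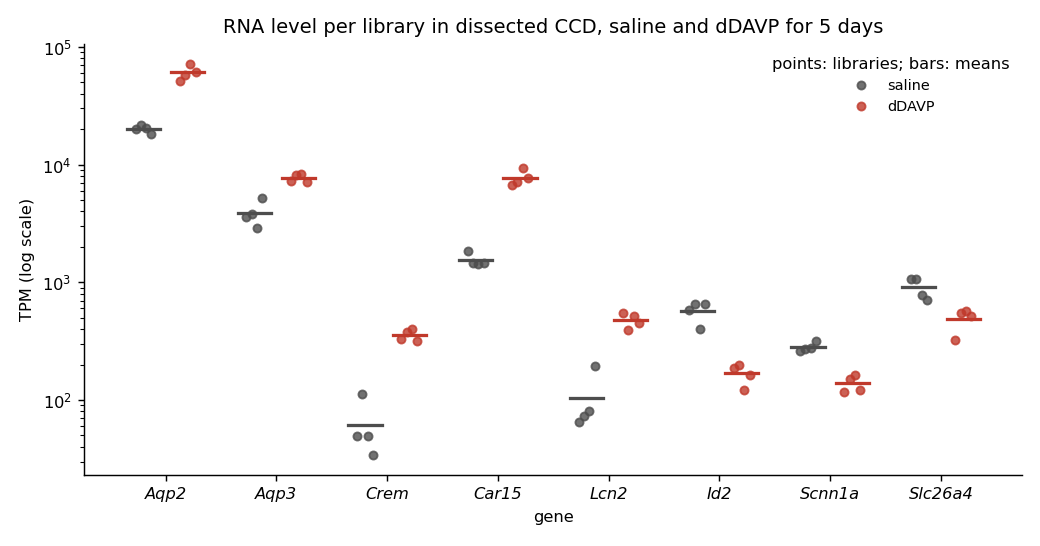
Expression of Aqp2, Aqp3, Crem, Car15, Lcn2, Id2, Scnn1a and Slc26a4 in TPM on a log axis, with points for the 4 saline and 4 dDAVP libraries and bars for the group means. The dDAVP libraries lie above the saline libraries for the genes that rose and below them for Id2 and Scnn1a; Slc26a4 also did not overlap but did not pass by limma (adjusted p = 0.106).

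The principal cell genes did not move as one group. Of 16 measured genes for principal cell transport and hormone response, Aqp2 and Aqp3 rose, Scnn1a fell and 13 did not pass, while 6 rose and 2 fell when adjusted over the list alone. Avpr2, the V2 receptor, was at 953.8 TPM with saline and 1450 TPM with dDAVP (log2 0.61, adjusted p = 0.199). Scnn1b and Scnn1g, the β and γ subunits of the sodium channel, had log2 fold changes of -0.51 and 0.02 (adjusted p = 0.22 and 0.983), and Aqp4 had 1.57 (adjusted p = 0.334). The list ranked higher than other genes by camera (adjusted p = 0.022), but adjusted p = 0.38 with an estimated correlation, and the call was lost without saline library 1 (adjusted p = 0.0533) and without dDAVP library 3 (adjusted p = 0.0566). Of 9 principal cell markers, 2 rose, again Aqp2 and Aqp3, none fell and 7 did not pass, with 4 that rose and 1 that fell when adjusted over the list alone (camera adjusted p = 0.00088, and adjusted p = 0.38 with an estimated correlation). For Aqp3 the call was lost in 6 of the 8 fits that left out 1 library, with adjusted p up to 0.119, and for Scnn1a in 6 of 8, with adjusted p up to 0.0933. These 6 fits were those without saline 1, saline 2, dDAVP 1, dDAVP 2, dDAVP 3 and dDAVP 4.

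Shared and type B markers of intercalated cells, the acid-base transporting cells of the duct, were lower as lists. Of 10 shared intercalated cell markers, Car15 rose, Car12 fell and 8 did not pass by limma, and 1 rose and 7 fell when adjusted over the list alone (8 of 10 below 0, camera adjusted p = 0.00421, and adjusted p = 0.475 with an estimated correlation). The ammonia transporters Rhbg and Rhcg had log2 fold changes of -1.01 (limma adjusted p = 0.0769) and -0.60 (limma adjusted p = 0.104), and the authors' deposited table called Rhcg lower (DESeq adjusted p = 0.003625). None of 6 type B intercalated cell markers passed by limma, and 4 fell when adjusted over the list alone (5 of 6 below 0, camera adjusted p = 0.000415, and adjusted p = 0.266 with an estimated correlation). Slc26a4, the apical chloride-bicarbonate exchanger pendrin, was at 907.3 ± 190.6 TPM with saline and 488.2 ± 113.1 TPM with dDAVP (log2 -0.90, SE 0.22). Hmx2, Slc4a9 and Insrr had log2 fold changes of -1.02, -0.94 and -1.15 (limma adjusted p = 0.0755, 0.0758 and 0.118). The authors' deposited table called Slc26a4 and Insrr lower (DESeq adjusted p = 0.04686 and 3.601e-07). None of 5 type A markers passed by limma, 1 fell when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.702); Slc4a1, the basolateral anion exchanger of type A cells, had a log2 fold change of -0.06. It was 0.00 after rescaling by median of ratios.

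By list scores, the mean difference in log2 was 0.41 for principal cell markers and -0.70 for type B markers (exact permutation p = 0.0286 each, adjusted p = 0.0858 over 6 scores). It was 0.21 for principal cell transport and hormone response (exact permutation p = 0.0571, adjusted p = 0.114), -0.286 for shared intercalated cell markers (exact permutation p = 0.0857, adjusted p = 0.129) and -0.13 for type A markers (exact permutation p = 0.4, adjusted p = 0.4). Whether the type A and type B lists differed from each other was not tested. For Car12 the call was lost in 5 of the 8 fits that left out 1 library, those without saline 1, saline 2, dDAVP 1, dDAVP 3 and dDAVP 4, with adjusted p up to 0.147, and after rescaling by median of ratios (adjusted p = 0.0596).

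**Figure D2:**
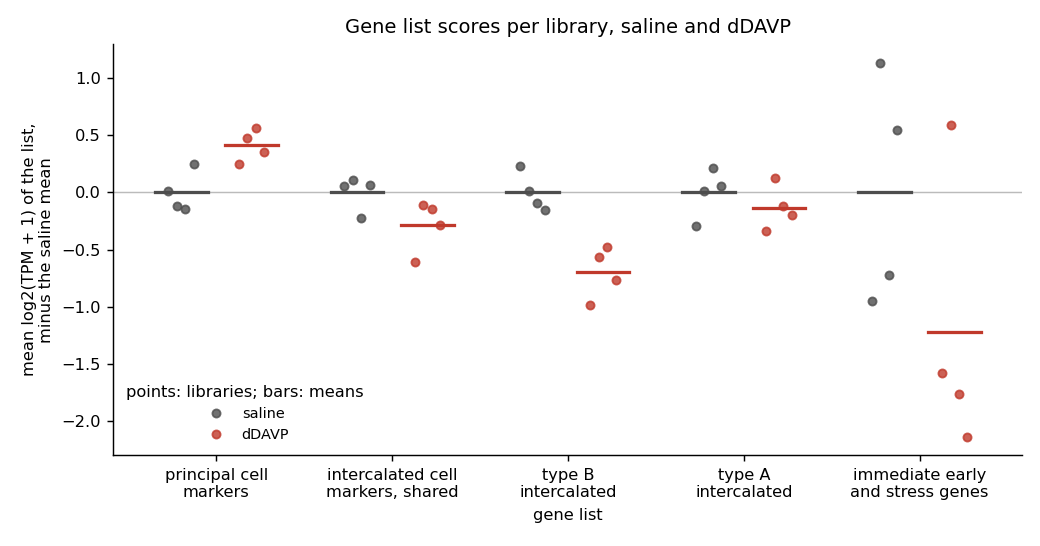
Score of 5 gene lists per library, the mean log2(TPM + 1) of the members minus the saline mean, with points for the 4 saline and 4 dDAVP libraries and bars for group means. Type B intercalated cell markers lay lower in the dDAVP libraries by a mean of -0.70, and immediate early genes by -1.22 with overlapping groups.

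Immediate early genes, which respond within minutes to stimulation and to tissue handling, were lower as a list under dDAVP. Of 16 measured genes none passed by limma, 6 fell when adjusted over the list alone, and 15 of 16 log2 fold changes were below 0 (camera adjusted p = 7.59e-05, and adjusted p = 0.602 with an estimated correlation). Fos, Junb, Jun and the heat shock gene Hspa1a had log2 fold changes of -2.66, -2.58, -2.35 and -1.33 (limma adjusted p = 0.26, 0.112, 0.108 and 0.192), and the authors' deposited table called Hspa1a lower (DESeq adjusted p = 0.02908). dDAVP library 2 stood with the saline libraries: Fos was at 1715 TPM in it and 60.03 to 151.9 TPM in the other dDAVP libraries, against 643.3 to 2076 TPM with saline. The score differed by -1.22 (exact permutation p = 0.2, adjusted p = 0.24). Without dDAVP library 2, Fos, Junb and Jun passed over all genes, with log2 fold changes of -3.70, -3.31 and -2.96 (limma adjusted p = 0.00496, 0.00496 and 0.00913).

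Genes of oxidative phosphorylation were lower and cytosolic ribosomal proteins higher as lists, with no member past the threshold over all genes or over the list alone. Among 39 oxidative phosphorylation genes, 32 had a log2 fold change below 0, among them Atp5a1 (-0.47), Ndufs1 (-0.67), Atp5b (-0.46) and Cyc1 (-0.35) (camera adjusted p = 0.00504, and adjusted p = 0.646 with an estimated correlation). That call was lost without saline library 1 (adjusted p = 0.116) and without dDAVP library 2 (adjusted p = 0.0848). Among 34 ribosomal protein genes, 30 were above 0, among them Rpl26 (0.83), Rps19 (0.79), Rps25 (0.71) and Rpl5 (0.67) (camera adjusted p = 7.36e-07, and adjusted p = 0.266 with an estimated correlation).

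Signalling and trafficking genes around AQP2 gave few calls among those measured. Only genes above 10 TPM in every library were listed. This left 11 of 27 cAMP and PKA components, 6 of 18 CREB target genes and 12 of 20 trafficking genes. A gene that rose from a lower saline level could not be seen. Of 11 cAMP and PKA signalling components, Crem rose and 10 did not pass, with 2 that rose when adjusted over the list alone (camera adjusted p = 0.0793, and higher at adjusted p = 0.0454 without saline library 3). Pde3b, a cAMP phosphodiesterase, was at 26.23 ± 11.11 TPM with saline and 91.72 ± 27 TPM with dDAVP (adjusted p = 0.0657). It passed after rescaling by median of ratios, after quantile normalization and without saline library 4 (adjusted p = 0.0345, 0.0207 and 0.027). Of 6 CREB target genes, Crem rose and 5 did not pass, with 1 that rose and 1 that fell when adjusted over the list alone. Their median log2 fold change was -0.43 whereas camera ranked them upward (adjusted p = 0.902). None of 12 genes of the AQP2 trafficking machinery passed (camera adjusted p = 0.795), with Anxa2 at 0.70 and Vamp3 at -0.80, and none of 12 genes of the β-catenin complex and adherens junction passed (camera adjusted p = 0.902), with none when adjusted over either list alone. Ctnnb1 itself was at 259.7 ± 19.44 and 259.6 ± 51.11 TPM (log2 -0.02, adjusted p = 0.977), with a log2 fold change of 0.04 after rescaling by median of ratios. The authors' deposited table marked 15 genes as Wnt/Fzd targets, of which Id2 passed in that table and by limma. In all, 7 of 22 lists passed by camera, 3 higher and 4 lower, and 0 passed with an estimated correlation, where camera gave 2 lists at an unadjusted p below 0.05, the ribosomal proteins and the type B markers.

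The ATAC-seq comparison asked where accessibility differed between saline and dDAVP. In the authors' deposited table, 18480 of 270806 peaks passed an adjusted p of 0.05, of which 2290 had a higher and 16190 a lower signal with dDAVP, so that 87.6% were lower. Of 18508 promoter-TSS peaks, 31 were called higher and 4774 lower. Of 138486 intron peaks, 1108 were higher and 5568 lower, and of 95574 intergenic peaks, 1058 were higher and 3241 lower. The strongest peak that gained signal lay between Aqp2 and Aqp5 on chromosome 15, from 99585782 to 99587989 (mm10), 1237 bp beyond the end of Aqp2. Its log2 signal was 8.94 with saline and 9.89 with dDAVP (n = 3 per group, log2 fold change 1.06, the authors' adjusted p = 2.52e-11).

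Around that peak the other called peaks were lower with dDAVP. The main Aqp2 promoter peak, from 99578305 to 99579420, was not called (log2 fold change -0.22, adjusted p = 0.399). A pair of intron peaks of Aqp2 had -0.89 and -1.08, and the Aqp5 promoter had -0.72 (adjusted p = 0.00724). At Car15, a peak annotated as intron 1 on chromosome 16, from 17837337 to 17838583, gained signal (0.50, adjusted p = 0.0141). It overlapped the gene and reached past its boundary at 17838186. Intron 1 is the first intron of a gene, so this boundary is likely the start of Car15. A peak 4036 bp from the gene, from 17830241 to 17831240, had 0.46 (adjusted p = 0.0213). These were among 15 peaks called higher at a mean log2 signal above 7, chosen after their values were seen. In this set, peaks in introns of Ttc39b, Mad1l1 and Camta1 had log2 fold changes of 1.38, 1.31 and 1.17.

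Of the 12 fixed genes, 9 had a promoter peak. Of their 13 promoter peaks, 4 were called and all 4 were lower. These belonged to Aqp3 (-0.69, adjusted p = 0.000231), Scnn1b (-0.61, adjusted p = 0.00121), Scnn1g (-0.45, adjusted p = 0.031) and Lef1, a transcription factor of the Wnt pathway (-0.81, adjusted p = 0.00882). The 5 largest gains were listed at 0 with saline, so no fold is given. They lay in or nearest to LOC108167416 (chromosome 7, 30274996 to 30275396, dDAVP log2 signal 3.43), Gm13090 (3.03), Dlg2 (2.88), Mir6401 (2.83) and Lrit3 (2.79). The 5 largest losses were listed at 0 with dDAVP and lay in intron 1 of Nedd4l, a ubiquitin ligase of the epithelial sodium channel (chromosome 18, 64919621 to 64919783, saline log2 signal 2.77), at the Gpr22 promoter (2.54), in Far1os (2.51), in the 3' UTR of Sik1, a kinase induced by cAMP (2.18), and in Mgst2 (2.17).

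The direction followed the strength of the peak. The median log2 fold change was 0.64 at a mean log2 signal of 0 to 1, -0.02 at 2 to 3 and -0.50 at 7 to 9. At 2 to 3, 685 peaks were higher and 155 lower, and at 7 to 9, 13 were higher and 7662 lower. The floor was uneven: 25627 peaks were listed at 0 with saline and 12636 with dDAVP. Of the higher calls, 421 were listed at 0 with saline, and of the lower calls, 30 were listed at 0 with dDAVP. The gains of weak peaks therefore rest in part on values at the floor. After the median of each signal bin was subtracted, a step chosen after the data were seen, 17036 of the called peaks kept their sign, 2290 higher and 14746 lower. The bin medians were negative from a signal of 2 up, so higher calls there could not lose their sign. No peak was tested again after this step. Only group means were at hand, so the spread between libraries could not be weighed and no library could be left out.

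**Figure D3:**
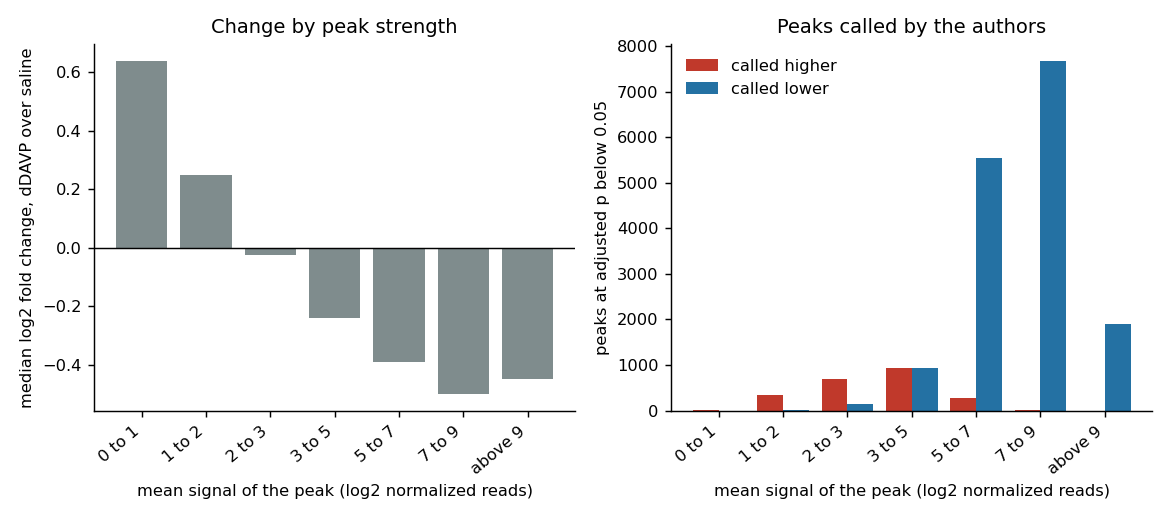
ATAC-seq peaks by mean log2 signal, showing the median log2 fold change of dDAVP over saline per bin and the number of peaks called higher and lower. The median passed from 0.64 in the weakest bin to -0.50 at a signal of 7 to 9, and most calls among strong peaks were lower.

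**Figure D4:**
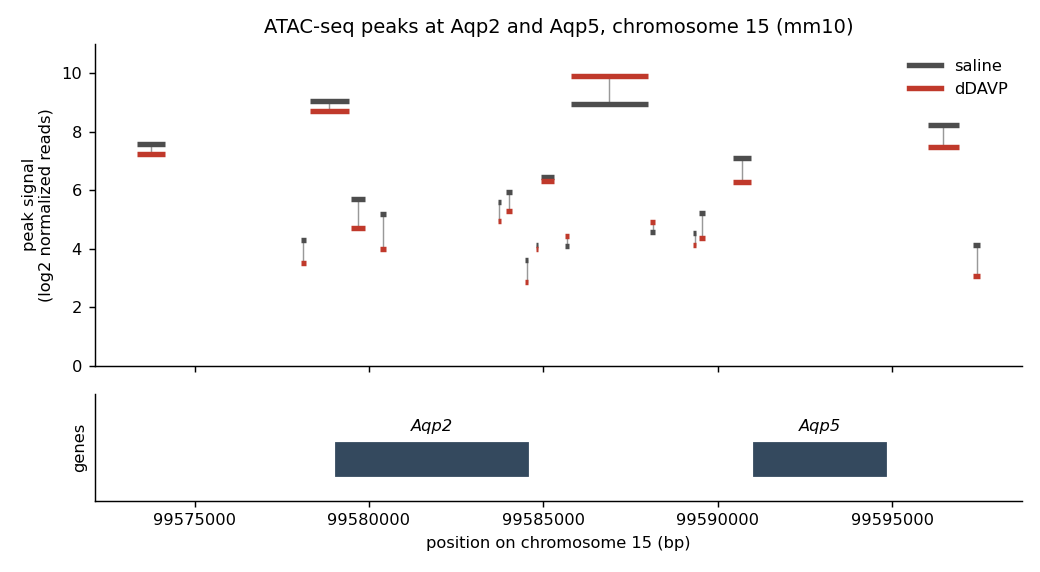
ATAC-seq peaks around Aqp2 and Aqp5 on chromosome 15 (mm10), with the mean log2 signal of each peak in the 3 saline and the 3 dDAVP libraries and the gene bodies drawn as boxes. The peak from 99585782 to 99587989 had 8.94 with saline and 9.89 with dDAVP.

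Accessibility and expression changes were compared for 3744 genes with RNA and a promoter peak. Of 17 promoters of genes that rose in RNA, 0 were called higher, 6 lower and 11 not called by the authors' DiffBind table. The promoters of both Crem and Aqp3 were lower by a log2 of -0.69, and that of Car15 was at 0.79 without a call. That Car15 promoter peak was weak (mean log2 signal 1.93). The stronger peak called higher at one end of Car15 (log2 0.50, the authors' adjusted p = 0.0141) was annotated as intron 1, so it was not counted here. It likely spans the start of the gene, so the count of 0 may leave out a gain at the Car15 promoter. Of 6 promoters of genes that fell, 0 were called higher, 5 lower and 1 not called. Few promoter peaks were called higher at all, 31 of 18508, so these counts do not show whether promoters followed the RNA. The promoters of the genes that rose had a median log2 fold change of -0.39, higher than 99.7% of random promoter sets matched on signal (random median -0.51). Those of the genes that fell had -0.63, higher than 7.4% of the random sets. Across genes, which are not independent replicates, the Spearman correlation of both changes was 0.0269, and its standard deviation over the other 34 splits of the RNA-seq libraries was 0.0256. With 1 RNA-seq library left out it ran from 0.0163, without saline 4, to 0.0435, without saline 3.

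The comparison of MT with WT asked what a mutation of a PKA target site of β-catenin does in the CCD. Ctnnb1, the gene of β-catenin (chromosome 9, 120933400 to 120960507), was at 371.6, 385, 399.6 and 392.1 TPM in units WT 1 to 4 and at 368, 376.1, 382.4 and 406.6 TPM in units MT 1 to 4 (log2 fold change -0.01, SE 0.05, adjusted p = 0.999). A point mutation need not alter the level of the RNA, so this level does not check the label. Aqp2 was at 17260 ± 7155 TPM in WT and 15650 ± 4642 TPM in MT (SD, n = 4 units, log2 -0.10, SE 0.29, adjusted p = 0.999). Aqp3, Avpr2, Scnn1a, Scnn1b and Scnn1g had log2 fold changes of 0.05, 0.06, 0.12, 0.05 and 0.05, and Slc26a4 and Slc4a1 had -0.04 and 0.14. Aqp4 had 0.35. The Wnt target genes Axin2 and Lef1 stayed below 1 TPM in every unit.

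No gene passed among the 15013 tested by limma. At an unadjusted p below 0.05 there were 683 genes, against 751 by chance, the smallest adjusted p was 0.376, and the groups did not overlap for 453 genes, 3.02%, where chance gives 2.86%. With all 24 libraries, limma gave 1 gene with the unit as a random block and 28 genes, 19 higher and 9 lower, with the libraries taken as independent. The 10 genes of smallest p, with 1 predicted gene model left aside, did not pass and included Anp32a, a nuclear phosphatase inhibitor, at 50.52 ± 5.233 TPM in WT and 26.7 ± 3.512 TPM in MT (log2 -0.90, SE 0.11), the gene called with the random block (adjusted p = 0.00142). Others were S100a14 (log2 0.78), Ctla2a (-0.57), Ube2e1 (0.24), Mthfd2l (0.33), Dus4l (-0.63), Gnb4 (-0.29), Aurkb (0.81) and Smim8 (0.24). Commd1b had 2.58 TPM in WT and 17.98 TPM in MT (log2 2.61, SE 0.45). It may be a copy of Commd1, and reads shared with that gene were not examined, so its value is uncertain. Leaving out 1 unit gave 1 gene without WT 3, 2 without WT 4, 1 without MT 2 and 5 without MT 4.

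**Figure D5:**
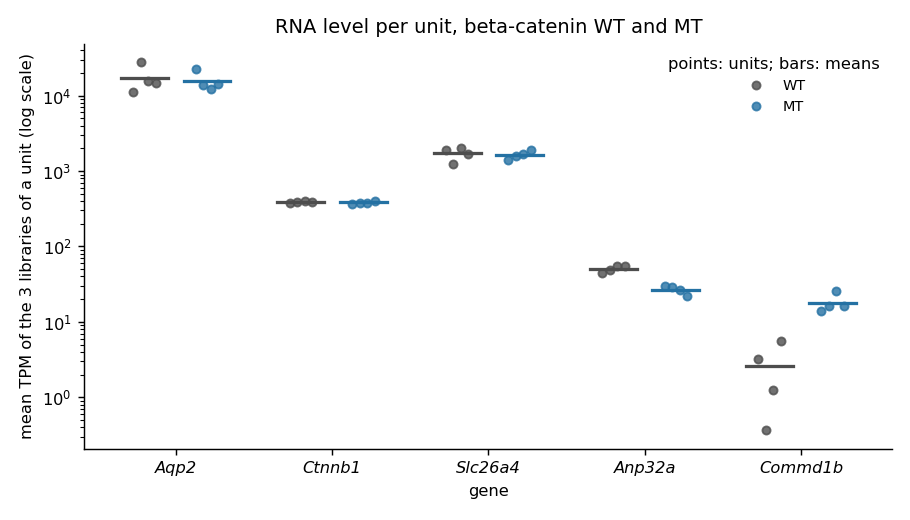
Expression of Aqp2, Ctnnb1, Slc26a4, Anp32a and Commd1b in the 4 WT and 4 MT units, in TPM on a log axis, with each point the mean of the 3 libraries of a unit and bars for group means. Anp32a lay at 44.26 to 55.02 TPM in WT and 21.78 to 29.74 TPM in MT, and none of these genes passed over all genes tested.

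Cell cycle genes were higher as a list in MT: none of 23 passed, 6 rose when adjusted over the list alone, and 22 of 23 were above 0 (camera adjusted p = 5.87e-11, and adjusted p = 0.64 with an estimated correlation). Aurkb and Top2a, which act in mitosis, were at 2.02 and 2.41 TPM in WT and 4.34 and 4.57 TPM in MT, and Mcm3 and Mcm2, of the replicative helicase, had log2 fold changes of 0.52 and 0.20. The cell cycle score differed by 0.39 (exact permutation p = 0.114, adjusted p = 0.285 over 5 scores). Genes of the β-catenin complex and adherens junction (20 measured, camera adjusted p = 0.45), β-catenin target genes (10 measured, camera adjusted p = 0.288) and principal cell transport genes (17 measured, camera adjusted p = 0.413) did not pass as lists, and none of their members did, also when adjusted over each list alone.

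Erythroid, thick ascending limb and proximal tubule transcripts were lower as lists in MT. Erythroid transcripts (6 measured, of which Slc4a1 is also a type A intercalated cell marker) had none past the threshold and 2 that fell when adjusted over the list alone (camera adjusted p = 8.7e-05, and adjusted p = 0.64 with an estimated correlation). Hbb-bs, a β-globin gene, was at 138, 94.1, 5295 and 40.49 TPM in WT 1 to 4 and at 0.38, 0.40, 1.33 and 47.19 TPM in MT 1 to 4. Single libraries carried several of these means, with 15900, 20 and 7.85 TPM in the highest to lowest library of WT 3, 118, 2 and 1.16 TPM in WT 4 and 134, 4.76 and 2.49 TPM in MT 4. With the median TPM over the libraries of a unit the list still passed (adjusted p = 0.00354). The list score differed by -3.20 (exact permutation p = 0.0286, adjusted p = 0.143). All 7 thick ascending limb markers were below 0 (camera adjusted p = 0.000249, and adjusted p = 0.87 with an estimated correlation), with no call with the median TPM over the libraries of a unit (adjusted p = 0.332). Among them Cldn16, Cldn10, Slc12a1 and Egf had log2 fold changes of -1.24, -1.87, -2.80 and -2.80, and Umod had a mean of 862.6 TPM in WT 1, carried by 1 of its 3 libraries (2550 TPM, against 25.1 and 17.1 TPM in the others). In WT 4 it was at 1390 TPM in 1 library and at 53.3 and 26.4 TPM in the others. The score differed by -1.68 (exact permutation p = 0.171, adjusted p = 0.285). All 11 proximal tubule markers were below 0 (camera adjusted p = 0.00282, and adjusted p = 0.875 with an estimated correlation), with no call without WT 3 (adjusted p = 0.353) or without MT 1 (adjusted p = 0.0784). Their score differed by -1.14 (exact permutation p = 0.343, adjusted p = 0.429). No member of these tubule lists passed over all genes or over the list alone.

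The remaining 6 lists past the threshold by camera had no member past it, over all genes or over the list alone. Mitochondrially encoded transcripts (7 measured) were higher, with mt-Nd2 at 0.41 and mt-Nd6 at 0.36 (camera adjusted p = 0.00292, and adjusted p = 0.875 with an estimated correlation), with no call without WT 2 (adjusted p = 0.149) or MT 4 (adjusted p = 0.142). Glycolysis genes (16 measured) were higher, with Pgam1 at 0.30 (camera adjusted p = 0.0098, and adjusted p = 0.875 with an estimated correlation), with no call without WT 1, WT 4 or MT 4 (adjusted p = 0.145, 0.0576 and 0.146). Cholesterol synthesis genes (20 measured) were higher, with Msmo1 at 0.24 (camera adjusted p = 0.0222, and adjusted p = 0.875 with an estimated correlation), with no call without WT 2, WT 4, MT 1 or MT 4 (adjusted p = 0.124, 0.136, 0.123 and 0.42) or with the median TPM over the libraries of a unit (adjusted p = 0.072). Endothelial markers (9 measured) were higher, with Pecam1 at 0.25 (camera adjusted p = 0.0222, and adjusted p = 0.875 with an estimated correlation), with no call without WT 3, WT 4, MT 1, MT 3 or MT 4 (adjusted p = 0.242, 0.233, 0.0532, 0.156 and 0.17).

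Immediate early genes (20 measured) were lower in MT, with Dusp1 at -0.78 and Jun at -0.56 (camera adjusted p = 0.0098, and adjusted p = 0.902 with an estimated correlation), with no call without WT 1, WT 4 or MT 4 (adjusted p = 0.721, 0.377 and 0.682) and a score difference of -0.335 (exact permutation p = 0.571). CREB target genes (15 measured) were lower, with Pck1 at -1.37 and Per1 at -0.48 (camera adjusted p = 0.0222, and adjusted p = 0.875 with an estimated correlation), with no call without WT 1, WT 4, MT 1 or MT 4 (adjusted p = 0.323, 0.145, 0.0532 and 0.246). The CREB target list shares Fos and Dusp1 with the immediate early list, so these results are not independent. After rescaling by median of ratios, the glycolysis, cholesterol synthesis, immediate early and CREB target lists no longer passed (adjusted p = 0.1, 0.0666, 0.0666 and 0.0666). In all, 10 of 34 lists passed, 5 higher and 5 lower, with 5 passing without WT 4 and 5 without MT 4, and 0 passed with an estimated correlation, where camera gave 2 lists at an unadjusted p below 0.05, the cell cycle genes and the erythroid transcripts.

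The MT and dDAVP effects were compared across the 5031 genes of both tables, which had been normalised separately. The 28 genes that rose under dDAVP had a median MT over WT log2 fold change of 0.06 and the 7 that fell had 0.01, and 2 and 0 of them had an unadjusted p below 0.05. The Spearman correlation across genes was 0.0508. It was -0.00157 without saline library 3, 0.115 without saline 4, 0.0105 without dDAVP 1, 0.0255 without dDAVP 2 and 0.0853 without dDAVP 4. It was 0.0333 without saline 1 and 0.0353 without saline 2. No overlap of calls could be tested because MT against WT gave 0 calls by limma. Whether the WT and MT units had received dDAVP was uncertain. Their Aqp2 lay at 11230 to 27630 TPM, below the 51770 to 72250 TPM of the dDAVP libraries. The values therefore do not show whether the mutation alters the response to dDAVP.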

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

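The tests of a single offset in the ATAC-seq signal, of the handling of the tubules and of the position of the β-catenin units between saline and dDAVP were chosen only after the result was seen.

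Single samples stood far from the other 3 of their group in 16 of 258 groups of 4 samples, where chance gives 12.9, about 1 in 20. The value given is the gap to the nearest of the others divided by the range of the group. In the dDAVP table, saline library 3 lay apart for Eva1b (0.938, 19 TPM against 64 to 69.2 TPM), Ckmt1 (0.859, 1170 TPM against 1440 to 1490 TPM) and Vps35, a subunit of the retromer (0.89, 148 TPM against 108 to 112 TPM). Car15 was higher in saline 1 than in the other saline libraries (0.895, 1860 TPM against 1430 to 1470 TPM). Cdk18 was lower in dDAVP 3 (0.911, 126 TPM against 177 to 183 TPM), Slc26a4 lower in dDAVP 1 (0.858, 321 TPM against 522 to 565 TPM), Jun higher in dDAVP 2 (0.889, 233 TPM against 36.5 to 45 TPM) and Pde3b lower in dDAVP 4 (0.834, 52.1 TPM against 97.3 to 110.0 TPM) than in the other dDAVP libraries.

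In the β-catenin table, S100a14 was lower in WT 3 (0.911, 11.6 TPM against 15.1 to 15.5 TPM), Dus4l lower in MT 3 (0.835, 6.03 TPM against 7.63 to 7.99 TPM) and Kcnj10, a potassium channel of the basolateral membrane, higher in MT 4 (0.927, 21.7 TPM against 18.8 to 19 TPM). Globin transcripts stood apart in single units. In MT 4, Hbb-bs (0.852, 47.2 TPM), Hba-a1 (0.838, 20.6 TPM), Hbb-bt (0.897, 1.69 TPM) and Hba-a2 (0.894, 1.25 TPM) were above the other MT units, which reached at most 1.33, 0.95, 0.11 and 0.09 TPM. Hba-a2 was also higher in WT 3 (0.865, 289 TPM against 2.28 to 4.99 TPM).

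Strong ATAC-seq peaks had lower signal with dDAVP. A single normalization offset between the groups is argued against as the whole cause, because the median log2 fold change of weak peaks exceeded that of strong peaks by 0.47, more than the 0.2 allowed. Peaks listed at 0 in 1 group were not left out of the weak peaks. The median also fell from -0.24 at a signal of 3 to 5 to -0.50 at 7 to 9. A lower signal over background in the dDAVP libraries would lower promoter and distal peaks alike at matched strength. The median difference between them over 5 signal bins was -0.089, within the 0.2 allowed. It ran from -0.17 at a signal of 5 to 6, where promoters had -0.52 and distal peaks -0.34, to 0.046 above 9. The 0.2 allowed is wide beside changes of this size, so a lower signal over background stays possible but is not singled out. Accessibility that followed RNA cannot be told apart from it. The promoters of genes that rose lay above 99.7% of random sets. Those of genes that fell lay above 7.4%, which is not below the lowest 5%. Group means only were at hand, so an effect of dDAVP on accessibility stays open as well.

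Immediate early genes were lower under dDAVP as a list by camera (adjusted p = 7.59e-05), but the list did not pass with an estimated correlation (adjusted p = 0.602) and its score gave an exact permutation p of 0.2, so the change itself is uncertain. Lower promoter accessibility specific to these genes is argued against, because 71.2% of random promoter sets matched on signal lay below the median of their 17 promoters. These promoters did lose signal, with 15 of 17 called lower in the authors' deposited table, but no more than promoters of like signal. The ATAC-seq libraries were other libraries than the RNA-seq libraries. Handling of the tubules, which induces these genes, could add to the difference: the 3 libraries of a β-catenin unit differed in the score by a median range of 0.702, against a group difference of -1.22. That range is neither as large as the difference nor below 0.5 of it. A range of single libraries and a difference of group means are also unlike measures. In the dDAVP comparison itself, the score ran from 7.278 to 9.359 with saline and from 6.094 to 8.817 with dDAVP. Handling and an effect of dDAVP therefore cannot be told apart.

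The β-catenin libraries carried a dDAVP label, while Aqp2 lay at 11230 to 27630 TPM in the units, around the 18070 to 21870 TPM of the saline libraries and below the 51770 to 72250 TPM of the dDAVP libraries. On an axis from the saline mean at 0 to the dDAVP mean at 1 over 34 genes changed by dDAVP, without Aqp2, the 8 units had a median of 0.0256 (-0.0463 to 0.201), against -0.0483 to 0.0807 for saline and 0.97 to 1.05 for dDAVP libraries. The saline and dDAVP libraries had served to choose these genes and to set the axis, so their own narrow ranges follow in part from that choice. A random difference between the separately normalised tables is argued against, because the mean signed distance from the dDAVP level was -1.6 on the log2 scale, where random gene sets gave -0.288 to 0.18. The random sets were not chosen for a change under dDAVP, so part of this distance may come from the choice of the genes. The values are consistent with mice that had not received dDAVP, as the name of the table says, which remains a hypothesis. A β-catenin colony that responded less to dDAVP stays open as a biological explanation and was not tested.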

How the results depend on the processing

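Removing saline libraries 3 and 4 together, the median TPM over the libraries of a unit and the centring of ATAC-seq peaks on their signal bin were chosen only after the result was seen. The 35 genes of the dDAVP comparison became 7 to 47 when 1 library was left out, the lowest without dDAVP 3 and the highest without saline 4, and 8 (7 higher, 1 lower) with a replicate block by number. Whether the numbers pair the libraries could not be decided. Residuals of equal number correlated by 0.19, 0.23, 0.087 and -0.15 for numbers 1 to 4. The highest correlations with another number were 0.022, 0.019, 0.19 and 0.1. Pseudocounts, rescaling, quantile normalization and a robust fit gave 34 to 38 genes. The filters removed no gene of this table. Without saline 3 and 4 there were 42 genes, 28 of them shared. Over 17 alternatives, the 60 named genes gave 1020 values, of which 997 kept their direction, 71 lost and 7 gained the call, and 23 took the other direction without a call. The 7 lists stayed 5 to 9 when 1 library was left out, 7 after rescaling and 8 without saline 3 and 4, but 0 passed with an estimated correlation.

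For MT against WT, 0 genes became 0 to 5 when 1 unit was left out, 1 with the unit as a random block over 24 libraries and 28 with independent libraries. The last takes the libraries of a unit as separate replicates, which the labels neither state nor exclude. The correlation within a unit that limma estimated for the random block was 0.229. The count stayed 0 with a replicate block, with the median TPM and under the other settings. The 10 lists became 6 after rescaling by median of ratios, 5 to 11 when 1 unit was left out, 9 with the median TPM and 0 with an estimated correlation. The correlation of the MT and dDAVP effects ran from -0.00157, without saline 3, to 0.115, without saline 4, so its sign was not fixed. The 18480 peaks became 7603 at an adjusted p below 0.01, 723 higher and 6880 lower, by the stricter threshold itself. For the other changes the cause was not tested.

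The alternatives for read counts, and every alternative for ATAC-seq that needs values per library (normalization, filter, pseudocount, leaving out a library, replicate block), were not run. No paired analysis was possible for ATAC-seq because only group means were at hand. Depth was unknown, and no limit of detection was set for any gene or peak.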

Other observations

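The tests of peaks near genes that rose, of the share taken by Aqp2 and of the splits for the counts of genes were chosen only after the result was seen.

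Further lists of the dDAVP comparison held single genes that passed. Of 8 corticosteroid response genes, Lcn2 rose, Scnn1a fell and 6 did not pass (camera adjusted p = 0.5), and of 10 tubule injury genes Lcn2 rose and 9 did not by limma (camera adjusted p = 0.746), while the authors' deposited table also called Krt7 lower (DESeq adjusted p = 0.0308). Of 13 glycolysis genes, Ldha, lactate dehydrogenase A, rose from 1535 ± 213.9 to 2861 ± 292.4 TPM and 12 did not pass (camera adjusted p = 0.293). Unfolded protein response genes (15 measured, camera adjusted p = 0.0638), TGF-β and extracellular matrix genes (9 measured, camera adjusted p = 0.0793), cholesterol synthesis genes (7 measured, camera adjusted p = 0.702), mitochondrially encoded transcripts (7 measured, camera adjusted p = 0.5), tonicity response genes (5 measured, camera adjusted p = 0.948) and collecting duct transcription factors (12 measured, camera adjusted p = 0.902) had no member past the threshold over all genes by limma. Of these lists, the unfolded protein response passed higher in 5 alternatives (adjusted p from 0.00869 to 0.0485), TGF-β and extracellular matrix genes lower without dDAVP library 2 (adjusted p = 0.04) and mitochondrially encoded transcripts lower without dDAVP library 4 (adjusted p = 0.033). The authors' deposited table called the transcription factor Gata2 lower (DESeq adjusted p = 0.02056). When adjusted over the list alone, 1 rose and 1 fell among the corticosteroid response genes, the tubule injury genes and the transcription factors each, 1 rose among the glycolysis genes and the tonicity response genes each, and none of the other lists of this paragraph had a member that passed.

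In MT against WT, connecting tubule markers (7 measured, camera adjusted p = 0.291), distal convoluted tubule markers (5 measured, camera adjusted p = 0.747), macrophage and leukocyte markers (11 measured, camera adjusted p = 0.987) and principal cell markers (10 measured, camera adjusted p = 0.45) did not pass as lists, but connecting tubule markers passed lower with a replicate block (adjusted p = 0.0224) and without WT 2 (adjusted p = 0.000341), and principal cell markers higher without WT 2 (adjusted p = 0.0194). Type A and type B intercalated cell markers had camera adjusted p = 0.572 and 0.632, and the type B markers passed lower without WT 2 (adjusted p = 0.0386).

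Gained ATAC-seq peaks may lie near genes whose RNA rose under dDAVP. Of 27 placed genes that rose, 12 had a gained peak within 50 kb, namely Scg5, Cdk18, Car15, Arg2, Dab1, Ache, Btc, Ddit4l, Aqp2, Prom1, Mal2 and Adh1. Without Aqp2 and Car15, whose peaks had been seen, it was 10 of 25, against a median of 3 in 10000 random gene sets matched on the number of nearby peaks, of which 0 reached 10. Matched on TPM in place of peaks, 1 of 10000 sets did. Within 10 kb it was 6 of 25 (11 sets as high) and within 100 kb 11 of 25 (49 sets as high). Near Ache, which encodes acetylcholinesterase, a peak 19038 bp away on chromosome 5, from 137268151 to 137269209, had a log2 fold change of 0.92. For the 7 genes that fell, the median centred log2 fold change of non-promoter peaks within 50 kb was -0.21, below the random range of -0.19 to 0.058, with 1.24% of sets lower, and 7.1% lower within 100 kb. These values go with nearby elements that changed with the RNA, a hypothesis found and tested on the same data. The count of gained peaks kept promoter-TSS peaks, the only gained peaks of Scg5 and Arg2, 17138 and 26208 bp from these genes. Saline log2 signals of the gained peaks were 6.12 for Scg5 and 6.13 for Arg2. They were 0 for Btc and Prom1, 0.394 for Mal2 and 0.406 for Adh1. The random sets were not matched on peak signal.

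Most genes had a slightly lower TPM under dDAVP, with a median log2 fold change of -0.06 over all genes. With Aqp2 left out and the other genes rescaled to 1 total, the median was 0.011, so the share taken by Aqp2 may account for this shift.

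Genes linked to the edited Ctnnb1 locus might carry small differences between MT and WT. Within 10 Mb of Ctnnb1, 6.38% of the tested genes (6 of 94) had an unadjusted p below 0.05 by limma, against a median of 4.26% and a 95th percentile of 8.51% in 135 windows of as many genes. With 40 windows as high, linkage and chance cannot be told apart.

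Splits of the 8 samples of a table into 4 and 4 set how large a result arises without the real groups. For the genes changed by dDAVP, 1 of 35 splits, the real one, gave as many as 35, and the highest other gave 0. That is the smallest share that 35 splits can reach, and the other splits mix saline with dDAVP libraries. Chance is therefore argued against but not excluded. For the lists under dDAVP, 3 of 35 splits gave as many as the real 7, with a highest other of 7, so chance is not excluded. For MT against WT, all 35 splits gave at least the real 0 genes, and the highest other, WT 1, WT 4, MT 2 and MT 3 against the rest, gave 26, which may point to a structure of the samples. The next highest gave 5, and no cause of such a structure was tested. For its lists, 18 of 35 splits gave as many as the real 10, with a highest other of 17. The correlation of the MT and dDAVP effects was as far from 0 as 0.0508 in 30 of 35 splits, with a highest other of 0.319. That of accessibility and RNA was as far from 0 as 0.0269 in 13 of 35 splits, with a highest other of 0.0707. Chance is not excluded for these last 3.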
